A study of Mus musculus with 2 samples.

How the data were processed

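Spermatogenic cells from the testes of ICR mice aged 6 weeks were used for chromatin immunoprecipitation with an antibody against H1t, a testis-specific linker histone, after enzymatic fragmentation, per the labels' protocols. The series holds 2 libraries, an H1t immunoprecipitate and an input. A peak list was analysed for the H1t library, and the input was not analysed here. With 1 library there is no replicate, so no p-value is given. Reads were aligned with Bowtie 1.1.2 to mm10, per the submitters' processing notes. The peak caller, its threshold and the treatment of reads with several matching positions are not given in the sources used here. The deposited list gives a chromosome, start, end, name and score for each peak. The names have the form that MACS writes, and the lowest score is 50. The score is the authors' own value per peak and served to describe, rank and filter peaks within this list. Read depth is not known, so no counting interval is given.

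Positions were compared with the GENCODE M21 annotation (Ensembl 96) of GRCm38, the assembly called mm10, and are printed counted from 1. Ribosomal and transfer RNA genes came from a RefSeq table of the same assembly. Peaks on chromosomes 1 to 19, X and Y were analysed. Each midpoint was assigned to the first matching class among promoter (1000 bp upstream to 100 bp downstream of any annotated start site), 5′ UTR, coding sequence, 3′ UTR, other exon, intron and intergenic sequence. Observed numbers were divided by the mean of 200 random placements of the same peak widths on the same chromosomes. Intervals are 95% bootstrap intervals from 1000 resamples of 10 Mb genome blocks, and a ratio was called when its interval excluded 1. They describe variation along the genome within this library, not variation between animals. Assembly gaps were not excluded by sequence, and stretches of at least 500 kb with neither peak nor gene were left out.

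For gene lists, peaks per 100 kb were taken over the gene body and 10 kb on each side. The list's median was placed among 10000 random lists matched on gene type and length decile, and a list was called below percentile 2.5 or above 97.5. With 27 lists, at most 1.35 calls are expected by chance if the members of a list are independent. Members of clustered families can lie within each other's flanks and share peaks, so chance calls can be more frequent for such lists. Where 5% or more of the matched medians were 0 no lower call was possible, which left 14 of the 27 lists that could be called lower. The lists, the main tests and the named-gene rule were fixed before the data were examined. That rule took coding genes: the 10 of at least 10 kb with the largest covered share, the 10 with the highest score within 1 kb of the start site, and the 10 of at least 100 kb with the fewest peaks per 100 kb, ties by symbol. It also took the 3 densest members of each list, the linker histone genes, the ribosomal RNA loci and the 10 highest-scoring peaks; the text prints a selection of these, and some genes the rule takes are not reported here. The GC content of exons and pseudogenes was computed from the annotated transcript sequences. The division by GC content, the division of X and Y by annotation class, and the counts by gene type, gene density and chromosome end were chosen after the data were seen.

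The procedures were tested on simulated data built from the 76434 peak widths. In 10 simulations a true coding ratio of 4 gave a mean of 4.04 and a true ratio of 2 gave 2.02, and true X to autosome ratios of 0.4 and 0.7 gave 0.396 and 0.699. With no effect, 96.7% of 90 intervals for annotation classes, start sites and neighbours included 1. The simulated peaks came from the same random placement that the comparison uses. They do not cluster or follow GC content as the real peaks do, so the rate for such peaks was not tested. Of 200 random lists of 30 genes, 3.5% were called, and 74% were called higher after their density was doubled. These lists were drawn at random from coding genes, so the rate for clustered families was not tested. Alternatives covered the score threshold, the overlap rule, the windows, the chromosomes, the placement and the matching of lists. Repeat content, GC content of peaks and sequence copy number need a genome sequence, which was not used here, and were not computed. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.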

Results

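The series addressed the genome-wide distribution of the linker histone H1t in mouse spermatogenic cells. The H1t library had 76546 peaks, of which 76434 lay on chromosomes 1 to 19, X and Y. They covered 62.3 Mb in all, and those on these chromosomes took 2.34% of the analysed sequence at 28.7 peaks per Mb. Peak width had a median of 700 bp with quartiles of 573 and 912 bp. The authors' score had a median of 74.04, quartiles of 58.32 and 108.42, and a maximum of 3100, reached by 6 peaks. No value below has a replicate.

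The first comparison set the chromosomes against each other, since X and Y are silenced in male meiosis. X carried 21.02 peaks per Mb and Y 5.33, against 30.1 on the autosomes. The ratio was 0.697 for X (95% interval 0.633 to 0.762) and 0.177 for Y (0.0821 to 0.298). Single autosomes ran from 26.7 peaks per Mb on chromosome 13 to 34.0 on chromosome 4. Chromosomes 4 (ratio to the other autosomes 1.14) and 15 (1.12) lay above 1 and chromosome 13 (0.882) below, and the other autosomes were not called. On Y, density was 18.8 peaks per Mb in the first 10 Mb and 10.8 in the first 4 Mb (41 peaks). It was between 0.9 and 9.3 in the following 10 Mb blocks, and 28.4 between 90 and 91 Mb (24 peaks). The cause of the lower density on Y was not tested, and sequence copy number was not computed.

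Peaks at start sites and in exons were almost missing on X. A peak lay within 1 kb of the start site of 6 of 948 coding genes on X (0.633%) and of 0 of 183 on Y, against 5036 of 20807 on the autosomes (24.2%). Among these 6 genes were Asmt, the last enzyme of melatonin synthesis (best score 415.15), Fmr1nb (89.79) and Tex28 (82.22). Coding sequence of X held 2 peak midpoints where the autosomal rate gives 167, a ratio of 0.0119 (0 to 0.0442). Both lay in Gm21887, at X 170010317 to 170011991 and 170018121 to 170020304, with scores of 494.35 and 817.41. Promoters of X had 21 midpoints against 224 at the autosomal rate (ratio 0.0939, 0.0503 to 0.161), and 5′ UTRs had 0 against 21.2. Intergenic sequence of X kept a ratio of 0.759 (0.664 to 0.847) and introns 0.727 (0.633 to 0.829). The Rhox cluster, X-linked homeobox genes of the reproductive tract, had 0 of 32 start sites with a peak, and the list of X-linked multicopy testis genes 0 of 74, of which 73 lie on X and 1 on chromosome 2. This division by annotation class was made after the data were seen, and the depth over X was not analysed here.

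**Figure D1:**
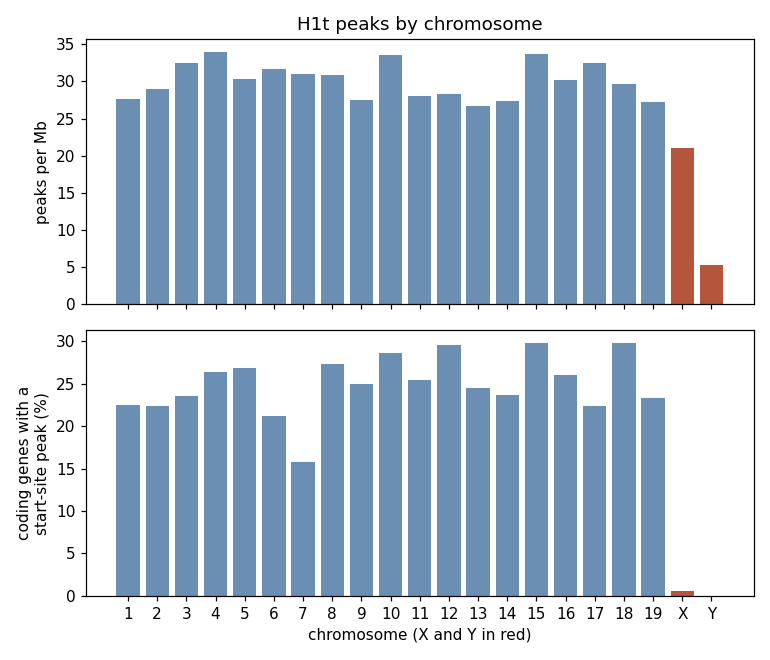
H1t peaks per Mb (upper panel) and the percentage of coding genes with a peak within 1 kb of the start site (lower panel) for each chromosome, autosomes in blue and X and Y in red. X has 21.02 peaks per Mb but 0.633% of its genes have a start-site peak, against 24.2% over the autosomes.

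The next comparison asked which parts of genes carried H1t peaks. Coding sequence held 3989 midpoints, 5.22% of all against 1.20% under random placement, a ratio of 4.33 (3.94 to 4.71). 5′ UTRs held 485 (ratio 6.28, 5.62 to 6.96) and promoters 5409 (1.94, 1.84 to 2.06). Intergenic sequence held 56.1% of midpoints against 51.5% (1.09, 1.06 to 1.12). Introns were lower, with 29.1% against 40.7% (0.714, 0.688 to 0.741), as were 3′ UTRs (0.676, 0.560 to 0.784) and other exons (0.638, 0.571 to 0.708). Median scores were 67.06 in coding sequence and 77.36 in intergenic sequence. The 3′ UTR ratio became 1.06 (0.935 to 1.19) when any overlap of at least 1 bp was counted, where the coding ratio was 1.71 and the 5′ UTR ratio 3.94. Among peaks above the median score the 3′ UTR ratio was 0.390. The coding ratio was 6.79 when at least 50% of the peak had to lie inside. The 5′ UTR ratio was 2.28 with promoters taken from 2000 bp upstream to 500 bp downstream.

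**Figure D2:**
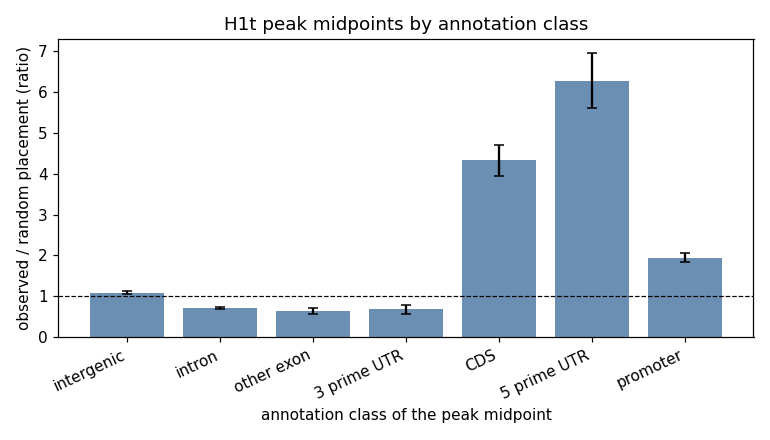
Ratio of observed H1t peak midpoints to the mean of 200 random placements for each annotation class, with 95% bootstrap intervals as error bars and a dashed line at 1. Coding sequence (4.33) and 5′ UTRs (6.28) stand highest, and introns, 3′ UTRs and other exons lie below 1.

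Exons with many G and C bases carried the coding peaks. Coding sequence was divided into 5 classes of similar size by exon GC content. The class with the highest GC content (58.8% or more) held 2895 midpoints where 161 were expected, a ratio of 18.0 (17.3 to 18.8). The class with the lowest (44.4% or less) held 8 where 192 were expected (0.0417, 0.0162 to 0.0725). The classes between had ratios of 0.119, 0.823 and 4.97 in rising order of GC content. Coding genes grouped in the same manner by first-exon GC content had a start-site peak in 3.14% of genes in the lowest class. Random placement gave 5.71% there (ratio 0.549, 0.431 to 0.687). In the highest class 43.8% had one, against 5.94% (ratio 7.37, 7.03 to 7.71). The input was not analysed here, so background by GC content was not measured.

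**Figure D3:**
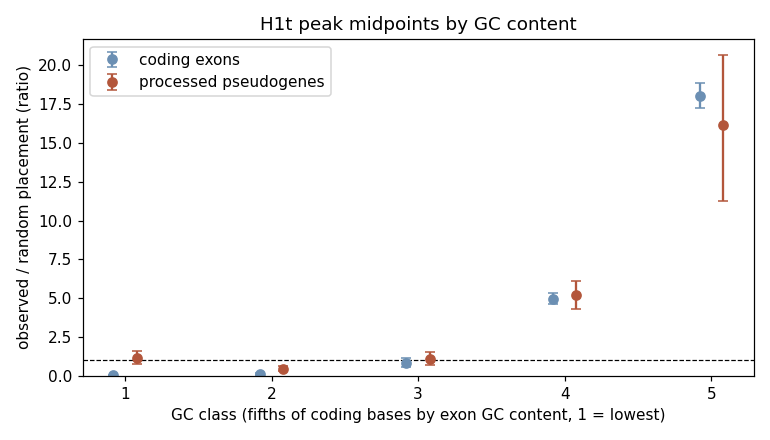
Ratio of observed H1t peak midpoints to random placement in 5 classes of rising GC content, for coding exons (blue) and for processed pseudogenes divided at the same GC values (red), with 95% bootstrap intervals. Coding exons rise from 0.0417 to 18.0, and pseudogenes have 1.12 in the lowest class, 0.452 in the second and 16.2 in the highest.

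Taken over all coding genes, start sites carried peaks more often than random placement gave. In the class of lowest first-exon GC content they carried fewer (ratio 0.549). A peak midpoint lay within 1 kb of 5042 of 21938 start sites (23.0% against 5.84%, ratio 3.93, 3.71 to 4.17). The ratio was 2.36 with a window of 2 kb. Density was 9.68 times the random level in the first 500 bp downstream and 2.66 times in the 500 bp upstream. Between 1500 and 1000 bp upstream it was 0.526 times the random level. The highest start-site scores belonged to Fcgr3, an Fc receptor gene (1397.55), Gm10801 (1155.36), Gm10800 (1154.48), AW822073 (1119.86) and Duxf3, a member of the Dux family of repeated homeobox genes (1014.81). Cebpa, a transcription factor of fat and myeloid cells, had a score of 396.75. Sequence copy number was not measured at any of these genes, so scores may gather reads from several copies. Peaks also lay close together, with 65.8% having a neighbour within 10 kb against 42.7% (ratio 1.54, 1.48 to 1.59), and this ratio was 0.991 (0.964 to 1.02) for neighbours within 100 kb.

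**Figure D4:**
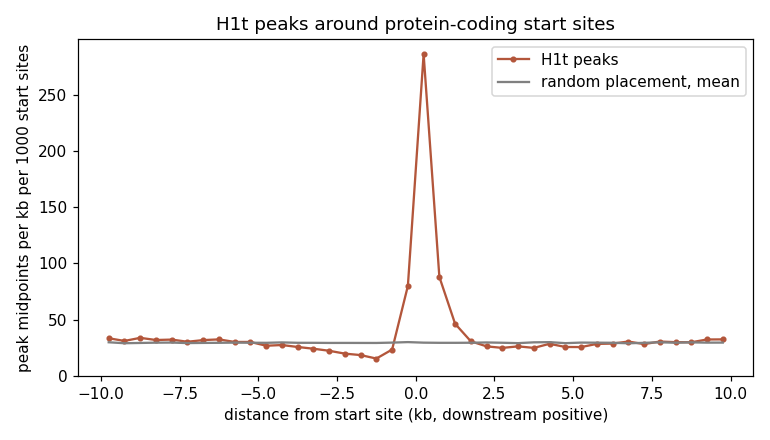
Peak midpoints per kb per 1000 start sites of coding genes, in bins of 500 bp over 10 kb on each side (red), and the mean of random placements (grey). Density peaks in the first 500 bp downstream at 286, against 29.6 at random.

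Germ-line gene groups were tested among the 27 lists. None of the spermatogonial, meiotic, spermatid or piRNA lists was called. The spermatogonial genes had a median of 2.19 peaks per 100 kb (percentile 41.8). A start-site peak was found in 10 of 25 (40% against 24.15% in matched genes), among them Lhx1 with 18.3 peaks per 100 kb. The meiotic genes had a median of 1.89 (percentile 21.6), led by the cohesin gene Rec8 (11.0) and the synaptonemal complex genes Sycp1 (10.2) and Syce1 (9.80). The spermatid genes had 2.56 (percentile 38.2), led by Pgk2 (18.5), and the piRNA pathway genes 2.40 (percentile 70.4), led by Henmt1 (12.2). Of the 11 linker histone genes, 6 had a start-site peak (54.5% against 17.9% in matched genes), with the highest score at H1fnt (148.03). The list's percentile was 75.2, or 98.99 over gene bodies alone, where it was called higher. Hist1h1t, which encodes H1t itself, and the spermatid linker histone gene Hils1 had 0 peaks within 10 kb. Such an absence is common, since only 52.9% of genes matched to this list had a peak there.

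Of the 27 lists, 6 carried more peaks than matched lists. The 39 Hox genes had a median of 8.51 peaks per 100 kb against 3.57 (percentile 100), with Hoxa2 at 22.3. The 58 protocadherin genes had 5.50 against 2.12 (percentile 100), with Pcdhb21 at 20.2. Core histone genes (4.81, percentile 99.99), keratin-associated protein genes (4.79, 99.97), cytochrome P450 genes (3.60, 99.3) and Sertoli cell genes (4.27, 97.6) were also called higher. Amh and Sox9, genes of the Sertoli cell programme, had 17.9 and 15.7. The core histone list's mean of 3.82 lay below the matched mean of 4.21, so median and mean differ in sign. The Hox call held under all 7 alternatives, and the protocadherin call ended with circular shifts (percentile 96.1). The core histone call ended with peaks above the median score (49.98), gene bodies alone (50), circular shifts (94) and means (29.9), and means in lists matched on transcript GC called it lower (2.22). The keratin-associated call ended with peaks above the median score (49.97), gene bodies alone (50) and means (89.7, or 91.9 with GC matching). For both lists the median was 0 with peaks above the median score and with gene bodies alone, as in nearly all matched lists. The cytochrome P450 call ended with gene bodies alone (36.4) and means (96.6), and the Sertoli call with transcript GC matching (94.1), means (91.7, or 84.8 with GC matching) and without genes on X and Y (97.2). The Leydig cell list was not called (percentile 26.4).

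Olfactory receptor genes, the large family of odorant receptors, carried fewer peaks than genes of matched length. Their median was 0 against 3.51 (percentile 0), since 46.0% of them had a peak against 55.3% in matched lists, and their mean was 3.29 against 4.12. A start-site peak was found in 18 of 1407 (1.28% against 14.2% in matched genes). Start-site shares here and below were matched on gene type and length, not on GC content. Vomeronasal receptor genes had a start-site peak in 0 of 328 against 20.03%, although their density was not called (2.78 against 2.80, percentile 47.7) and was called higher with circular shifts (99) and transcript GC matching (100). Zinc finger genes named Zfp were called lower (2.24 against 2.59, percentile 2.23). Both lower calls held with means (0 for olfactory receptors, 0.63 for Zfp genes) and without genes on X and Y (0 and 0.49). With transcript GC matching the Zfp call ended (50.23, or 48.45 with means). For olfactory receptors 99.99% of the GC-matched medians were 0, so no lower call was possible, and with means the percentile was 96.2. With peaks above the median score, gene bodies alone and circular shifts the medians were too often 0 for a lower call of either list (Zfp genes reached 85.5 with circular shifts). Among lists not called were the heterochromatin (percentile 16.2), imprinted (89.2), ribosomal protein (91.2), solute carrier (91.2), collagen (32.7), NADH dehydrogenase (11.8) and major urinary protein (29.4) genes. The medians of the beta-defensin (percentile 9.37), killer cell lectin-like receptor (3.06), Rhox (5.47), X-linked multicopy (10.3) and Y-linked multicopy (18.98) genes were 0, and so were too many matched medians for a lower call. With means all of these were called lower (0.03, 0.06, 1.16, 2.03 and 0.765), and with means and transcript GC matching only the killer cell lectin-like receptors (1.63) were, against 3.76, 5.28, 41.8 and 4.43 for the beta-defensin, Rhox, X-linked and Y-linked multicopy genes.

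**Figure D5:**
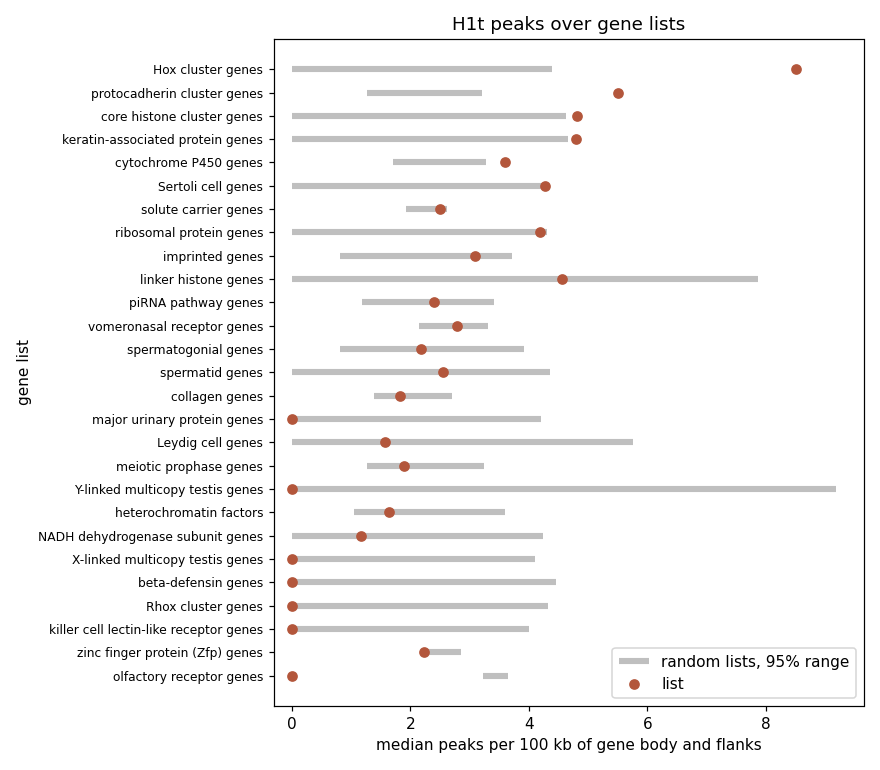
Median H1t peaks per 100 kb of gene body and flanks for each of the 27 gene lists (red points), with the 95% range of random lists matched on gene type and length (grey bars). Hox genes (8.51) and protocadherins (5.50) lie to the right of their ranges, and olfactory receptors (0) to the left, although not with means in lists matched on transcript GC as well (percentile 96.2).

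Among coding genes of at least 10 kb, the largest covered shares were those of Gm47283 on Y (72.8%), Map1s, a microtubule-associated protein gene (47.3%), Flg, which encodes the skin protein filaggrin (46.7%), Zfp651 (42.2%) and Ints1, an Integrator subunit gene (39.5%). Of 2492 coding genes of at least 100 kb, 155 had 0 peaks within 10 kb, 22 of them among the 117 on X. Abcc1, Adam23 and Add3 are examples from the start of the alphabetical order.

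Ribosomal RNA sequence held some of the strongest peaks. A peak of 6181 bp at chromosome 17, 39842920 to 39849100, over sequence derived from the 45S ribosomal RNA precursor, had the maximum score of 3100. The 5S gene array at chromosome 8, 123538784 to 123622046, held 38 peaks that covered 85.4% of its 83.3 kb, against 2.58% of chromosome 8. Of its 50 5S genes, 46 overlapped a peak, while 0 of 30 5S-type genes elsewhere did. The other peaks at the maximum score included introns of Tmem267 (chromosome 13, 119595471 to 119604565) and Gm21738 (chromosome 14, 19415298 to 19419781) and an intergenic site at chromosome 9, 124255928 to 124258100. Sequence present in several copies can gather reads from all of them, and copy number was not measured here.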

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

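The scaffold peaks below were counted after the peak list was seen. Outside the chromosomes used in the comparisons, 112 peaks lay on 29 unplaced or unlocalised scaffolds, a signal in sequence that no comparison used. The number expected there was not computed. Their median score was 82 and their highest 607.47. No explanation was tested for them.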

How the results depend on the processing

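Over 11 ratios of annotation classes, start sites, neighbours, X and Y, 82 of 84 alternative values kept their direction and their side of 1. Most of these alternatives used nearly the same peaks (258 were left out at scores of 500 or more). None of them addressed GC content, copy number or the input. With overlaps of at least 1 bp the 3′ UTR ratio was 1.06, and for neighbours within 100 kb the ratio was 0.991; the cause was not tested. Coding ratios ran from 1.71 to 6.79, start-site ratios from 2.36 to 4.05, X from 0.689 to 0.751 and Y from 0.176 to 0.190. Lists called lower fell from 2 to 0 with peaks above the median score, with gene bodies alone and with circular shifts, where only 1, 2 and 5 of the 27 lists could be called lower because too many matched medians were 0. They fell to 1 other list with transcript GC matching, and rose to 7 with means. Lists called higher fell from 6 to 2 with means. Some percentiles crossed the middle: cytochrome P450 36.4 with gene bodies alone, vomeronasal receptors 99 and Zfp genes 85.5 with circular shifts, vomeronasal receptors 100 with GC matching, Zfp genes 50.23 with GC matching, core histones 29.9 with means, and olfactory receptors 96.24, vomeronasal receptors 100 and core histones 2.22 with means and GC matching; the cause was not tested. Core histones at 49.98 and keratin-associated genes at 49.97 with peaks above the median score are ties of medians at 0, not crossings. Calls were gained, besides those of vomeronasal receptors and core histones above, by beta-defensin (0.03), Rhox (1.16), X-linked (2.03) and Y-linked multicopy (0.765) and killer cell lectin-like receptor genes (0.06, all lower) with means, the last also with means and GC matching (1.63), linker histones with gene bodies alone (98.99, higher), ribosomal protein (100) and solute carrier genes (99.4, both higher) with circular shifts, collagen genes with GC matching (2.43, lower) and killer cell lectin-like receptors without X and Y genes (1.995, lower). Matching on transcript GC, means, both together, the removal of X and Y genes, the basic annotation, stretches of 200 kb and removal of scores of 500 or more were added after the data were seen. Alternatives that need a genome sequence (placement matched on GC content or copy number, 50-mers, gene-region GC) were not run. Without read depth and input, weak peaks cannot be weighed against background.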

Other observations

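The counts by gene type, gene density and chromosome end, the 3′ UTR test for spliced RNA, and the tests of a uniform loss, of a loss by score and of lowered scores on X were chosen after the result was seen. MicroRNA genes overlapped peaks at 2.68 times the random level (156 of 2202, interval 2.13 to 3.26), and 10 of these 156 lay at chromosome 12, 109585789 to 109743496. Long non-coding RNAs from bidirectional promoters were at 1.90 (1.56 to 2.31), while lincRNAs were at 0.697 (0.663 to 0.729) and snoRNAs at 0.479 (0.269 to 0.752). Immunoglobulin V genes overlapped a peak in 0 of 218 cases, where 4.01% were expected. Transfer RNA genes were at 2.29 (0.410 to 5.97), which includes 1. Peak density was 31.9 per Mb in autosomal 1 Mb bins without coding genes, 26.6 with 6 to 10 genes and 39.4 with 21 or more. For peaks above the median score it was 16.7, 13.5 and 16.4. The first 5 Mb of the analysed sequence of the autosomes had a ratio of 1.19 (1.06 to 1.33) and the last 5 Mb 1.27 (1.08 to 1.47).

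The near absence of peaks at start sites, promoters and exons of X genes is the pattern most in need of follow-up, while introns of X kept a ratio of 0.727. A loss striking all X sequence alike was argued against by intergenic peaks, whose ratio of 0.759 (0.664 to 0.847) lies above the coding interval (0 to 0.0442). Lower GC content was argued against, for coding exons only, by a GC-matched ratio of 0.0248 (0 to 0.0980). Lower scores on X, as the single X copy of male cells would give, were weighed next. For a loss by score alone they were argued against as the whole cause. If the peaks that would have scored lowest were lost, at the same scores as among intronic peaks, coding peaks would keep a ratio of 0.686 (0.569 to 0.815) where 0.0119 was seen, and 5′ UTR peaks 0.751 (0.670 to 0.854) where 0 of 21.2 were seen. This takes the loss to depend on the score alone, and autosomal 5′ UTR and intronic peaks have median scores of 75.18 and 72.53. It also takes intronic peaks of X to be lowered by this loss alone. Scores divided by 2 would keep peaks of score 100 or more, 17.9% of autosomal coding peaks and 28.6% of intronic ones. X kept ratios of 0.0119 and 0.727. The peak caller is not given, so a loss of gene peaks by another rule than the score stays open. For the lower density of X as a whole, lower gene density was argued against by a ratio of 0.719 (0.655 to 0.781) in bins matched on gene count, and the single copy stays open. The X ratio above the median score over that below it was 1.17, and the bound set beforehand would exclude the single copy at 1 or more. That bound was wrong: autosomal intergenic scores lowered alike until the share seen on X remains give 1.06 when multiplied by 1 factor and 1.28 when lowered by 1 amount. Intergenic peaks of X gave 0.991 (0.926 to 1.06), but how the score falls with depth is not known. A chromatin state of the sex chromosomes may also be involved and was not tested.

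The 4-fold excess of peaks in coding sequence goes with GC content. Exons of the lowest GC class had a ratio of 0.0417, and processed pseudogenes in the GC range of the highest class had 16.2 (11.2 to 20.7), so the excess in GC-rich exons may follow GC content of any sequence; in the second class, where exons had 0.119, pseudogenes had 0.452 (0.286 to 0.663), and in the lowest class 1.12 (0.742 to 1.58), so they showed a lack of peaks in the second class and not in the lowest. Closeness to start sites as the whole cause was argued against. The ratio was 3.48 (3.10 to 3.84) more than 2 kb from any start site and 6.13 (5.57 to 6.71) nearer. These distance groups were not matched on GC content, so the gap between them cannot be credited to closeness apart from GC. Within each GC class, the ratio more than 2 kb away was below that of the whole class, with overlapping intervals. In the class below the highest it was 4.83 (4.44 to 5.22), against 4.97 (4.62 to 5.32) in that whole class. CpG content apart from GC as the whole cause was argued against by 13.9 in exons of high GC and low CpG. This ratio rose to 19.1 and 22.0 with more CpG. These exons were not matched on GC content within the highest GC class, so the rise cannot be credited to CpG content apart from GC. For reads from spliced RNA, the 3′ UTR ratio was 0.676, below 1 as the test set against them, and 1.06 with any overlap of 1 bp. That test cannot decide, because 3′ UTRs were not matched to coding exons on GC content, which goes with large differences in the ratio. A preference of H1t for GC-rich sequence and a GC bias of fragmentation, amplification or peak calling stay open, since the input was not analysed here, and no biological explanation was tested.

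Of the gene families above the matched lists, 5 of the 6 were still called higher when matched on transcript GC. The Sertoli list (percentile 94.1) was the exception. With means and GC matching 3 of the 6 were called higher (Hox, protocadherin and cytochrome P450), and core histones were called lower (2.22). For the Hox, protocadherin and cytochrome P450 lists, GC content of the transcript as the whole cause was argued against, as far as the calls stand. The protocadherin call ended with circular shifts (96.1), and the cytochrome P450 call with gene bodies alone (36.4) and means without GC matching (96.6). Genes of the GC-matched lists were drawn singly, while members of clustered families can share peaks. That matching used broad classes and left out the GC content of the 10 kb flanks, where peaks were counted as well. A part played by GC content of the region may therefore remain.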
